A study of Ovis aries with 20 samples.

How the data were processed

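mRNA of the semitendinosus muscle was sequenced in 20 sheep, 4 control fetuses, 4 IUGR fetuses, 6 control lambs and 6 IUGR lambs. Per the labels, RNA came from the middle of the muscle, ewes carried single Columbia-Rambouillet lambs, controls were pair-fed, and lambs were reared on milk replacer. The authors deposited a table of FPKM, fragments scaled to transcript length and to the number of mapped fragments, with no counts. Per the labels, Trimmomatic, TopHat2 2.0.1, Cufflinks 2.1.1 and Cuffdiff were used with build Oar_v3.1, and their roles and any further scaling between libraries are not stated. The upper quartiles of FPKM lie close together, between 7.53 and 7.92.

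The table holds 25000 genes for the 20 samples, of which 6440 are at 0 in every sample and 165 carry merged names. Of the names, 13539 matched a sheep gene symbol of a reference annotation, which was used for names only because it describes another assembly. Positions are those the table gives. Of the genes named, LRTM1, NRGN, TOP2A, SDHC, IGF2, GADL1, PC, ECI1, MCM7, GSK3B, MXI1, HK1, COQ4, STXBP5L, PRKCE and MAB21L2 are listed with a locus shared with other genes, and their bounds are not printed. MYH7 and MYH2 are not named in the table and INSR only in a merged name, so these were not analysed.

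Genes with an FPKM of at least 1 in at least 4 of the 20 samples were tested, 12220 genes, 9451 of them with a symbol. Values were log2(FPKM + 1), and changes, fold changes included, are on that scale. A model with the mean of each of the 4 groups was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend, 16 residual degrees of freedom), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The comparisons were IUGR against control in fetuses and in lambs, lambs against fetuses in controls and in IUGR, and the difference of the IUGR effect between lambs and fetuses. Directions are IUGR minus control, lamb minus fetus, and the IUGR effect in lambs minus that in fetuses. Body weights were compared with two-sided exact permutation tests in scipy 1.17.1.

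Gene lists written before the data were examined cover fibre types, developmental sarcomere, myogenic regulators, cell cycle, matrix, energy metabolism, insulin and IGF, atrophy, adrenergic, inflammatory, hypoxia, amino acid stress, heat shock, glucocorticoid, clock, ribosomal, imprinted and neuromuscular junction genes, and markers of other cell types. The 31 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a comparison. Camera with a correlation estimated from the data and fry, which asks whether the genes of a list move one way on balance, were the alternatives. The estimated correlation left 0 lists past the threshold in all 5 comparisons. In fetuses the matrix, fast fibre, fatty acid oxidation, tricarboxylic acid, oxidative phosphorylation, atrophy and glucocorticoid lists passed by camera but not by fry.

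The comparisons, tests, lists and naming rule were fixed before the data were examined. Named are the genes with a symbol, a mean FPKM of at least 1 and an adjusted p under 0.05 that had the 8 largest rises and 8 largest falls (5 and 5 for the difference of effects). Up to 4 passing members of each list by p, the 10 smallest p-values where fewer than 10 genes passed, and 18 genes fixed in advance for the IUGR comparisons were also named. Exceptions are marked as named after their values were seen.

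Depth is unknown without counts. Relative depth was estimated from the most frequent log2 ratio of FPKM values under 0.3 between libraries, where a value stands for few fragments, and was 0.93 to 1.64 in control fetuses, 1.28 to 1.62 in IUGR fetuses, 0.61 to 1.2 in control lambs and 0.62 to 0.93 in IUGR lambs. The median SD between libraries of a group on the log2 scale was 0.196 in control fetuses, 0.274 in IUGR fetuses, 0.216 in control lambs and 0.237 in IUGR lambs. The tests were tried on simulated data of the same groups with 12220 genes. Of genes shifted by 0.5, 1 and 2 on the log2 scale, 22%, 72.4% and 98% were recovered between fetuses, with 3.6% false calls, and 43.2%, 83.2% and 98.4% between lambs, with 6.2% false calls. Camera called 10 of 10 lists of 25 genes shifted by 0.4 and 0 of 200 unshifted lists. The simulated genes were drawn independently of each other. Correlations estimated in the fetal lists that passed ran from 0.066 (myogenic) to 0.844 (oxidative phosphorylation), so false calls among such lists are not covered.

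Alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 1, median-of-ratios and quantile scaling, no trend, array weights, only the groups compared, sex as a covariate, a block for the animal ID prefix, a block for the replicate number, and leaving out each library in turn. The prefix is the leading digits of the animal's number, whose meaning the labels do not give. Prefix 13, 14 and 15 occur in both lamb groups, in 2, 1 and 3 control lambs and in 4, 1 and 1 IUGR lambs, while in fetuses only prefix 11 occurs in both groups. Listed as female were 1 control fetus, 1 IUGR fetus, 3 control lambs and 4 IUGR lambs, and the other animals as male. The female IUGR fetus is IUGR fetus 0. Libraries of equal replicate number were not more alike within an age, so the numbers were not taken as pairs. No sample was left out. Tables were handled with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and figures drawn with matplotlib 3.10.9.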

Results

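RNA from the semitendinosus, a hindlimb muscle, was measured by mRNA sequencing with paired reads of 100 bases in 20 sheep. The groups were 4 control fetuses, 4 fetuses with intrauterine growth restriction (IUGR), 6 control lambs and 6 IUGR lambs. IUGR was induced by keeping pregnant ewes at 40 °C for 12 h and 35 °C for 12 h each day, at a dew point of 22 °C, from about day 40 of gestation to about day 94 for the fetuses and about day 89 for the lambs. Fetuses were sampled at gestational day 132 to 135 in controls and 133 to 135 in IUGR, and lambs at 26 to 39 days after birth in controls and 28 to 35 days in IUGR. Fetal weight was 1.25 ± 0.31 kg in IUGR and 3.54 ± 0.36 kg in controls (SD, n = 4 each), 35.4% of the control mean (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows). Lamb weight was 8.57 ± 1.13 kg in IUGR and 14.3 ± 1.36 kg in controls (SD, n = 6 each), 60.0% of the control mean (two-sided exact permutation p = 0.00216, the smallest that 6 against 6 allows). Birthweight of the same lambs was 2.83 ± 0.58 kg in IUGR and 4.55 ± 0.48 kg in controls (SD, n = 6 each), 62.3% of the control mean (two-sided exact permutation p = 0.00216).

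The deposited values are FPKM without counts, so the number of fragments per library is unknown and no counting interval can be given. The FPKM of a library summed to between 440014 and 784744, and 35.0% to 42.1% of the listed genes were at 0. Depth relative to the other libraries, estimated from the lowest FPKM values, ran from 0.93 to 1.64 in fetuses and from 0.61 to 1.2 in lambs. The 10 most abundant transcripts took 15.8% to 24.8% of the FPKM in fetuses and 21.9% to 30.1% in lambs. Libraries of a group correlated at 0.934 to 0.978 across genes, which are not independent replicates. Principal component 1, with 41.7% of the variance, parted fetuses from lambs, and component 2, with 12.2%, parted the control from the IUGR fetuses.

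**Figure D1:**
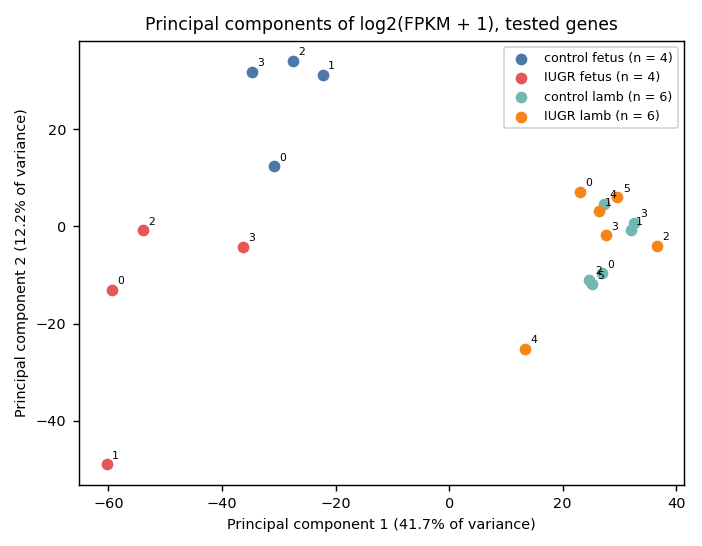
Scores of the 20 libraries on principal components 1 (41.7% of the variance) and 2 (12.2%) of log2(FPKM + 1), 1 point per library, coloured by group. Fetuses sit between −60.33 and −22.28 on component 1 and lambs between 13.35 and 36.55, and on component 2 the control fetuses sit between 12.43 and 34.04 and the IUGR fetuses between −48.97 and −0.75.

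Near term, the question was how the muscle transcriptome of growth-restricted fetuses differs from that of controls. The muscle of IUGR fetuses held more transcript of a carotenoid-cleaving enzyme and of the IGF receptor, and far less of fibrillar collagen and of the calcium buffer of fast fibres. BCO1, which encodes an enzyme that cleaves beta-carotene (Oar_v3.1 chromosome 14, 7297078 to 7327679), rose from a mean FPKM of 0.986 ± 1.29 in controls to 8.58 ± 1.68 in IUGR (SD, n = 4 each), 5.43-fold on FPKM + 1 (log2 2.44 ± 0.25 SE, limma adjusted p = 1.87e-05). IGF1R, the receptor for insulin-like growth factors (chromosome 18, 7159506 to 7219744), rose 3.68-fold from 14.7 ± 2.02 to 57.7 ± 16.4 (SD, n = 4 each; limma adjusted p = 6.35e-05). PVALB, the calcium buffer parvalbumin (chromosome 3, 180019348 to 180067626), fell by 3.31 on the log2 scale (SE 0.64), from 26.2 ± 19.7 to 1.32 ± 0.941 (SD, n = 4 each; limma adjusted p = 0.00317). In each of these 3 genes, 4 of 4 IUGR fetuses lay beyond all control fetuses.

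Of the 12220 genes tested in fetuses, 1900 passed an adjusted p of 0.05, 835 higher and 1065 lower in IUGR, and 441 of them differed by 2-fold or more. After quantile normalization 1147 were higher and 1140 lower. Among the largest rises were GALNT15, an enzyme of protein O-glycosylation (log2 2.44 ± 0.35 SE), DLK2 (2.20 ± 0.28), AGT, which encodes angiotensinogen (2.18 ± 0.44), and NDUFA4L2 (2.12 ± 0.42). The falls included CCDC80, a matrix protein (−2.70 ± 0.34 SE, from a mean FPKM of 43.6 ± 10.8 to 6.09 ± 2.77, SD, n = 4 each), FAM78A (−2.70 ± 0.37), CHRDL2, a secreted binding protein of bone morphogenetic proteins (−2.49 ± 0.48), LRTM1 (−2.31 ± 0.44), NREP (−2.17 ± 0.50) and MYL4, the embryonic myosin light chain (−2.22 ± 0.51). IUGR fetuses lay beyond all controls in 4 of 4 for GALNT15, DLK2, AGT, CCDC80, FAM78A, CHRDL2, LRTM1 and NREP, and in 3 of 4 for NDUFA4L2 and MYL4. Their adjusted p-values ran from 0.000238 for CCDC80 to 0.00837 for MYL4. LRTM1 shares its listed locus with another gene. The glucocorticoid-induced FKBP5 (3.04 ± 0.94 SE), CEBPD (2.20 ± 0.64), the cell cycle inhibitor CDKN1A (2.14 ± 0.67) and NRGN (−2.17 ± 0.67) also passed, at adjusted p of 0.0355, 0.0266, 0.0365 and 0.0352. Without IUGR fetus 1 these 4 were at 2.51, 1.62, 1.53 and −2.10 and no longer passed, and calls also ended without control fetus 1 (FKBP5 2.57, CEBPD 1.99, CDKN1A 2.07), control fetus 2 (FKBP5 2.38, CEBPD 1.99, CDKN1A 2.02, NRGN −1.21), control fetus 3 (FKBP5 3.05, CDKN1A 1.92, NRGN −2.33), IUGR fetus 0 (FKBP5 2.81, CEBPD 2.09) and IUGR fetus 2 (NRGN −2.11).

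**Figure D2:**
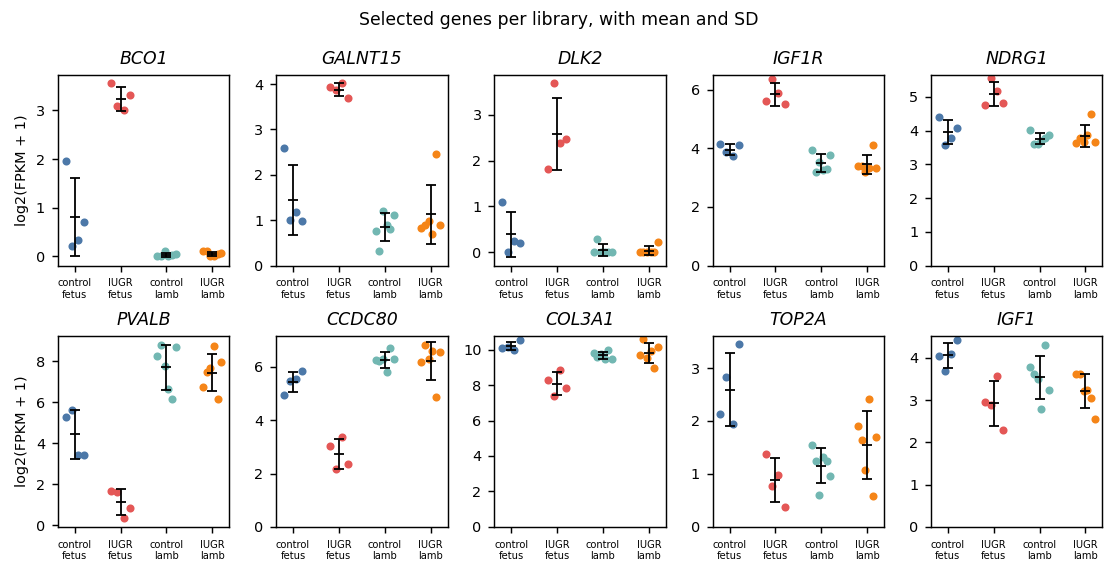
Log2(FPKM + 1) of 10 genes in every library, by group, with the mean and SD of each group on that scale. Before the log, mean FPKM of BCO1 is 0.986 in control fetuses and 8.58 in IUGR fetuses, and that of COL3A1 is 1194 and 292.

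Ribosomal protein and hypoxia response transcripts were higher in IUGR fetuses. Of 26 ribosomal protein genes, 17 rose and 0 fell (23 and 0 adjusted over the list alone), with a median log2 change of 0.58. RPS16 rose from a mean FPKM of 496 ± 76.2 to 785 ± 90.8 (SD, n = 4 each; limma adjusted p = 0.00388) and RPS19 by 0.75 on the log2 scale (SE 0.17, adjusted p = 0.00859). Camera gave the ribosomal list an adjusted p of 2.29e-10, and adjusted p = 0.588 with an estimated correlation. Its call ended with a block for animal ID prefix (median 0.12, adjusted p = 0.176). In fetuses this block compares IUGR fetus 0 alone with the 4 controls, as the other IUGR fetuses share no prefix with a control. The ribosomal count of 17 was 7, 3 and 6 without control fetus 1, 2 and 3, and 2 and 9 without IUGR fetus 1 and 3. Of 22 hypoxia response genes, 12 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.99 (camera adjusted p = 3.18e-06, adjusted p = 0.588 with an estimated correlation). Without IUGR fetus 1, 7 rose and the median was 0.63, and with the ID prefix block 1 rose but the median was 0.83 and the list call stood (adjusted p = 7.62e-05). Among the 12 were NDRG1 (log2 1.12 ± 0.20 SE, adjusted p = 0.00232), the vasodilator peptide ADM (1.41 ± 0.28, 0.00389), carbonic anhydrase CA9 (1.66 ± 0.34, 0.00431) and the pyruvate dehydrogenase kinase PDK1 (1.16 ± 0.25, 0.00645). ADM was beyond all controls in 3 of 4 IUGR fetuses.

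Connective tissue and proliferation transcripts were lower in IUGR fetuses. Of 29 extracellular matrix genes, 10 fell and 1 rose (13 and 2 adjusted over the list alone), with a median of −0.49 (camera adjusted p = 0.00083, adjusted p = 0.71 with an estimated correlation). COL3A1 fell from a mean FPKM of 1194 ± 219 to 292 ± 129 (SD, n = 4 each; limma adjusted p = 0.000614), COL1A2 fell by 1.98 on the log2 scale (SE 0.30) and COL1A1 by 1.41 (SE 0.29). The gene that rose, named after its values were seen, was the collagenase MMP14 (0.68 ± 0.20 SE, adjusted p = 0.0264), which no longer passed without control fetus 1 (0.59), control fetus 2 (0.66), IUGR fetus 1 (0.49) or IUGR fetus 2 (0.64). Of 12 genes for fibroblasts and fibro-adipogenic progenitors, 5 fell and 0 rose (6 and 0 adjusted over the list alone), with a median of −0.56 (camera adjusted p = 0.00842, adjusted p = 0.588 with an estimated correlation). The list lost its call with array weights (−0.44, adjusted p = 0.09). Of its genes, 3 fell without control fetus 1 or 2 or IUGR fetus 0 and 2 without control fetus 3 or IUGR fetus 1. The 5 genes were PI16 (−1.75 ± 0.27 SE), LUM (−1.50 ± 0.30), CD34, MFAP5 and, named after its values were seen, PRRX1. The calls of CD34, MFAP5 and PRRX1 (adjusted p 0.0184 to 0.0459) each ended without at least 3 of the 8 fetal libraries, among them IUGR fetus 1 (−0.56, −0.69 and −0.77). Of 24 cell cycle genes, 15 fell and 2 rose (16 and 2 adjusted over the list alone), with a median of −0.84 (camera adjusted p = 1.72e-06, adjusted p = 0.588 with an estimated correlation). Without control fetus 3 or IUGR fetus 1, 9 fell. With the ID prefix block 0 fell past the threshold (limma, 2477 genes in all at an unadjusted p under 0.05), though the median was −0.72 and the list call stood (adjusted p = 0.0016). With a pseudocount of 0.1 the median was −1.31. TOP2A fell by 1.71 (SE 0.35) and the spindle protein TPX2 by 0.93 (SE 0.18). AURKA, a mitotic kinase, rose by 0.78 (SE 0.13) and MCM7, named after its values were seen, by 0.57 (SE 0.14, 0.48 and no longer past the threshold without IUGR fetus 1).

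**Figure D3:**
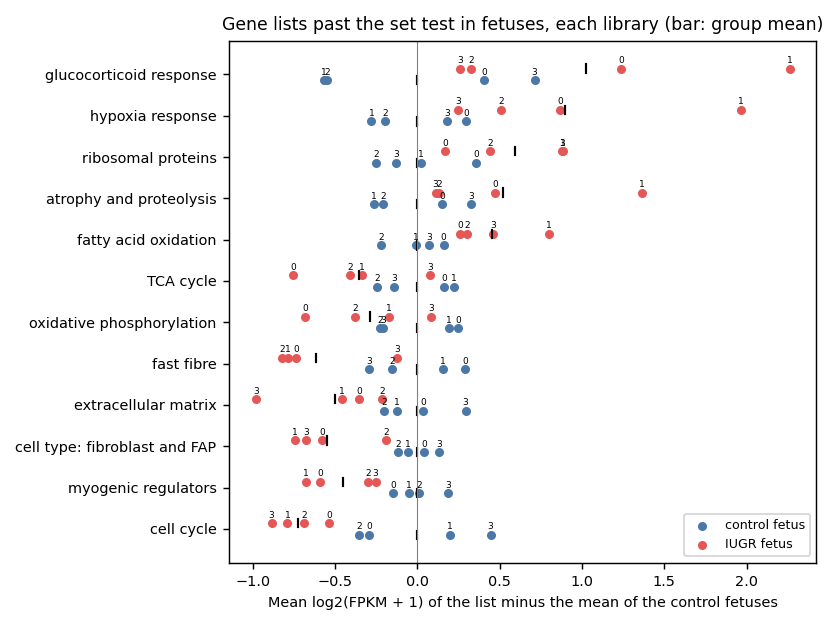
Mean log2 difference from the control mean, over the members of each of 12 gene lists, in each fetal library (points, n = 4 control and 4 IUGR). Cell cycle means run from −0.886 to −0.538 in IUGR fetuses and from −0.353 to 0.445 in controls, while in the ribosomal list IUGR fetus 0, at 0.167, lies inside the control range of −0.25 to 0.358.

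Fast fibre and myogenic regulator lists were also lower, while the slow fibre list passed only with the ID prefix block (median −0.98, camera adjusted p = 0.0093, and −0.54 for fast fibres). The fast and slow lists were not tested against each other. Of 13 fast fibre genes, 3 fell and 0 rose (4 and 0 adjusted over the list alone): PVALB, the calcium store protein CASQ1 (−1.56 ± 0.35 SE, adjusted p = 0.00764) and ACTN3 (−0.86 ± 0.24, 0.0224). ACTN3 no longer passed without control fetus 1 (−0.81), control fetus 2 (−0.81), IUGR fetus 1 (−0.65) or IUGR fetus 2 (−0.71). The fast fibre list (median −0.41, camera adjusted p = 0.00972, adjusted p = 0.71 with an estimated correlation) lost its call without control fetus 0 (−0.24, adjusted p = 0.0801). Without IUGR fetus 3, 5 of its genes fell. Of 19 myogenic regulators, 6 fell and 0 rose (6 and 0 adjusted over the list alone), with a median of −0.58 (camera adjusted p = 0.00436, adjusted p = 0.588 with an estimated correlation). In the myogenic list 2 genes fell without control fetus 1 or 2 or IUGR fetus 0, and 1 without control fetus 3 or IUGR fetus 1. The 6 genes included the satellite cell cadherin CDH15 (−0.58 ± 0.14 SE, adjusted p = 0.0104).

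Fatty acid oxidation genes were higher and tricarboxylic acid and oxidative phosphorylation genes lower by camera, but these lists were not tested against each other. By fry none of them passed (adjusted p = 0.0601, 0.249 and 0.444). Of 24 fatty acid oxidation genes, 7 rose and 0 fell (9 and 1 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.00842, adjusted p = 0.71 with an estimated correlation). UCP2 rose by 1.24 (SE 0.26, adjusted p = 0.00526) and ECI1 by 1.26 (SE 0.29, adjusted p = 0.00918), and the list lost its call without IUGR fetus 3 (0.25, adjusted p = 0.0756) and with the ID prefix block (−0.07, adjusted p = 0.954). Its count was 3 without control fetus 2 or 3 and 2 without IUGR fetus 1. Of 18 tricarboxylic acid cycle genes, 4 fell and 0 rose (4 and 0 adjusted over the list alone), with a median of −0.25 (camera adjusted p = 0.00842, adjusted p = 0.809 with an estimated correlation). OGDH fell by 0.91 (SE 0.23, adjusted p = 0.0136), but not past the threshold without IUGR fetus 1 (−0.77, 0.0642), and PC, CS and SDHC fell by 0.70, 0.66 and 0.82. The PC call (adjusted p = 0.018) ended without control fetus 1, 2 or 3 or IUGR fetus 1 (−0.63, −0.66, −0.66 and −0.68), and those of CS and SDHC (0.0459 and 0.0387) ended without each fetal library other than IUGR fetus 3 (CS −0.73 to −0.57, SDHC −0.86 to −0.69). Oxidative phosphorylation had 1 of 43 genes lower, SDHC, and 0 higher (0 and 0 adjusted over the list alone), with a median of −0.28 (camera adjusted p = 0.00436, adjusted p = 0.876 with an estimated correlation). Tricarboxylic acid genes past the threshold numbered 2 without control fetus 0 or IUGR fetus 0 or 2, 1 without control fetus 1, 2 or 3 and 0 without IUGR fetus 1 (limma), and oxidative phosphorylation genes 6 without IUGR fetus 3. The oxidative phosphorylation list lost its call without control fetus 0 (−0.18, 0.0631) or IUGR fetus 0 (−0.17, 0.141), and the tricarboxylic acid list without IUGR fetus 0 (−0.08, 0.144). The tricarboxylic acid median was also −0.16 without control fetus 1 and −0.38 without IUGR fetus 3, both past the threshold. With the ID prefix block both lists were further down (oxidative phosphorylation −0.63, 1.38e-12, tricarboxylic acid −0.74, 2.06e-08).

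Catabolic genes rose in part. Of 24 atrophy and proteolysis genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.52 (camera adjusted p = 0.00842, adjusted p = 0.71 with an estimated correlation). GABARAPL1, an autophagy gene, rose by 1.28 (SE 0.32, adjusted p = 0.014) and the muscle F-box gene FBXO40 fell by 1.24 (SE 0.24, adjusted p = 0.00312). Of 18 glucocorticoid response genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 1.02 (camera adjusted p = 0.00842, adjusted p = 0.71 with an estimated correlation). KLF15 rose by 1.35 (SE 0.35, adjusted p = 0.0163) and GLUL, glutamine synthetase, by 1.69 (SE 0.51, adjusted p = 0.0304). Without IUGR fetus 1 GABARAPL1 was at 0.95, KLF15 at 1.07 and GLUL at 0.91, none past the threshold. KLF15 also failed without control fetus 1 (1.15) or 2 (1.19), and GLUL without control fetus 1 (1.58), 2 (1.68) or 3 (1.69). Without IUGR fetus 1 both lists lost their call too (atrophy 0.30, adjusted p = 0.059, glucocorticoid 0.57, adjusted p = 0.0762) and 0 of their genes rose past the threshold (limma, 2720 genes in all at an unadjusted p under 0.05). The atrophy call also ended with the ID prefix block (0.41, adjusted p = 0.0669), and its count of rises was 2 without control fetus 1 or 3 and 1 without control fetus 2. The glucocorticoid count was 0 without control fetus 1 or 2 and 3 without control fetus 3 or IUGR fetus 0.

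In the insulin and IGF list, which did not pass by camera (median 0.21, adjusted p = 0.876 with an estimated correlation), 3 of its genes rose and 5 fell (6 and 6 adjusted over the list alone). The rises were IGF1R, GRB10 (0.84 ± 0.24 SE, adjusted p = 0.0231) and EIF4EBP1 (0.91 ± 0.25, 0.0215, named after its values were seen). The falls were IGFBP7 (−1.26 ± 0.20 SE, adjusted p = 0.00103), IGFBP5 (−1.41 ± 0.32, 0.00787), IGFBP4 (−1.07 ± 0.25, 0.0098), IGF1 (−1.14 ± 0.30, 0.0155) and, named after its values were seen, GSK3B (−0.49 ± 0.13, 0.017). IGF1 did not pass without control fetus 3 (−1.02, 0.0536) or IUGR fetus 1 (−1.13, 0.0503), nor GSK3B without the same libraries (−0.43 and −0.45). GRB10 failed without control fetus 1 (0.69) or 2 (0.78) or IUGR fetus 0 (0.79) or 1 (0.67), and EIF4EBP1 without control fetus 1 (0.90), 2 (0.80) or 3 (0.77) or IUGR fetus 1 (0.74). Of the other genes fixed in advance, MSTN (−0.97, adjusted p = 0.113), MYOG (−0.89, 0.125), MYOD1 (−0.79, 0.326), PAX7 (−0.02, 0.973), ADRB2 (−1.01, 0.0516), MYH1 (0.27, 0.377), IGF2 (0.21, 0.703), SLC2A4 (0.43, 0.179), FBXO32 (1.07, 0.404), PDK4 (3.74, 0.07), PPARGC1A (−0.32, 0.64) and TNFRSF1A (−0.10, 0.647) did not pass. The animals' ID numbers begin with 11 in all 4 control fetuses and IUGR fetus 0 and with 12 in IUGR fetuses 1, 2 and 3, and with a block for this prefix, which leaves IUGR fetus 0 as the only IUGR fetus compared, 263 genes passed in place of 1900. Of 74 fetal gene calls followed across the alternatives, 13 stood with that block (BCO1, GALNT15, AGT, FAM78A, CCDC80, CASQ1, COL3A1, OGDH, PHKG1, IGF1R, STAT1, ADM and PRRX1), and 33 with only the groups compared. With the block 3 oxidative phosphorylation and 2 tricarboxylic acid genes were lower, 1 gene each passed in the hypoxia, matrix, fibroblast and fast fibre lists, and 0 in the other 6 lists that had passed. As lists, 9 of the 12 kept their call with the block: hypoxia, cell cycle, oxidative phosphorylation and tricarboxylic acid at the medians given above, the matrix at a smaller size (−0.21, adjusted p = 0.0477), and fast fibre (−0.54, 0.0042), myogenic (−0.40, 0.0062), fibroblast (−0.53, 0.0242) and glucocorticoid genes (0.92, 0.0082). The count was 1035, 1001 and 1059 without control fetus 1, 2 and 3 and 673 without IUGR fetus 1.

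At about 30 days of age, the question was whether IUGR lambs still differ from control lambs. No gene passed in lambs: 0 of 12220 by limma at an adjusted p of 0.05, and 606 at an unadjusted p under 0.05. The smallest p-values belonged to XRCC5, a DNA repair gene (chromosome 2, 217109474 to 217195146, log2 0.44 ± 0.09 SE, beyond all controls in 6 of 6 IUGR lambs), and CYTIP (chromosome 2, 151149426 to 151177249, −1.10 ± 0.22, 5 of 6), both at an adjusted p of 0.39. TMPO, MAN2A2, COQ4, TRAF3IP3, STXBP5L, PRKCE, MAB21L2 and GCLM made up the 10 smallest, at the same adjusted p and log2 differences from −1.01 (TRAF3IP3) to 0.63 (MAB21L2). The genes fixed in advance did not pass either: IGF1 (−0.32), IGF2 (0.44), MSTN (−0.82), PAX7 (0.22), MYOD1 (0.43), MYOG (0.33), MYH1 (−0.06), ADRB2 (−0.10), SLC2A4 (0.08), FBXO32 (−0.12), PDK4 (1.64 ± 1.12 SE), IGFBP5 (−0.51), COL1A1 (0.33), PPARGC1A (−0.15) and TNFRSF1A (−0.04). In simulated data with the same groups, 83.2% of genes shifted by 1 on the log2 scale were recovered between lambs.

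Small shifts shared by the members of a list did appear in lambs, though 0 of their genes passed alone. All 43 oxidative phosphorylation genes were on the higher side in IUGR lambs (median 0.24, camera adjusted p = 2.23e-11, adjusted p = 0.904 with an estimated correlation). So were 22 of 24 cell cycle genes (0.24, 7.36e-07, adjusted p = 0.639 with an estimated correlation), 16 of 18 tricarboxylic acid cycle genes (0.19, 0.000849, adjusted p = 0.917 with an estimated correlation) and 11 of 12 nerve and Schwann cell genes (0.31, 0.000849, adjusted p = 0.639 with an estimated correlation). Of 15 circadian clock genes, 14 were on the lower side (median −0.28, camera adjusted p = 0.00034, adjusted p = 0.565 with an estimated correlation). Glycolysis (−0.17, 0.0106), fatty acid oxidation (0.15, 0.0153) and heat shock (0.10, 0.0299) passed by camera as well, with adjusted p = 0.917, 0.904 and 0.917 with an estimated correlation, and fry called 0 of the 31 lists in lambs. Calls ended without control lamb 0 (fatty acid oxidation 0.09), 1 (glycolysis −0.08), 2 (tricarboxylic acid 0.10, heat shock 0.11), 3 (glycolysis −0.15, heat shock 0.12) and 5 (fatty acid oxidation 0.11, heat shock 0.09). They also ended without IUGR lamb 1 (fatty acid oxidation 0.15, nerve 0.17), 3 (heat shock −0.09) and 4 (glycolysis −0.07). Further endings came with array weights (glycolysis −0.07, heat shock 0.08), with sex as a covariate (glycolysis −0.14, heat shock 0.10) and with the ID prefix block (nerve 0.15, heat shock 0.04). Medians that moved by over 1.5 times but still passed were those of oxidative phosphorylation (0.40) and the tricarboxylic acid cycle (0.33) without IUGR lamb 4, the tricarboxylic acid cycle without IUGR lamb 1 (0.12) and nerve genes without control lamb 3 (0.20). Heat shock was at 0.16 without control lamb 0, 0.175 without IUGR lamb 4 and 0.16 without IUGR lamb 5, and cell cycle at 0.48 with a pseudocount of 0.1. The matrix list, which had not passed (adjusted p = 0.171), passed as higher without control lamb 4 (0.17), IUGR lamb 2 (0.18) or IUGR lamb 4 (0.20) and without IUGR lambs 3 and 4 (0.10).

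The effect of IUGR was then compared directly between lambs and fetuses. Matrix and cell cycle transcripts that moved in IUGR fetuses did not move alike in IUGR lambs. BCO1 was 2.44 higher on the log2 scale in IUGR fetuses than in controls, and its IUGR effect was −2.42 ± 0.32 SE in lambs relative to fetuses (limma adjusted p = 0.00142), the only named gene still past the threshold with the ID prefix block (−2.73), where the fetal part rests on IUGR fetus 0. The effect was also lower in lambs for SNCG (−2.31 ± 0.39), NDUFA4L2 (−2.48 ± 0.54), DLK2 (−2.21 ± 0.36), GALNT15 (−2.16 ± 0.45) and IGF1R (−1.92, adjusted p = 0.0504 with that block), and higher for CHRDL2 (3.36 ± 0.61), CCDC80 (2.67 ± 0.43), COL3A1 (2.25) and TOP2A (2.11). PVALB (3.04 ± 0.82, adjusted p = 0.0411), MYL4 (2.70 ± 0.66, 0.0266) and SNAI3 (2.59 ± 0.67, 0.0339) passed too. The call of MYL4 ended without control fetus 1 (2.40), 2 (2.70) or 3 (2.72) or IUGR fetus 1 (2.54). Those of PVALB and SNAI3 ended without 11 and 8 of the 20 libraries, at 2.64 to 3.21 and 2.20 to 2.65. BCO1 and DLK2 were near 0 in lambs, at a mean FPKM of 0.024 and 0.038 in controls and 0.038 and 0.029 in IUGR. Their difference therefore comes from the fetal change, and an effect of IUGR in lambs could hardly show in them.

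In all, the IUGR effect differed in 614 genes, 367 higher and 247 lower in lambs, and after quantile normalization in 808, 408 higher and 400 lower. Camera called 10 of 31 lists, and with an estimated correlation 0, at an adjusted p = 0.725 for each. Cell cycle had 13 genes higher and 1, AURKA, lower (19 and 2 adjusted over the list alone, median 0.95, camera adjusted p = 1.63e-09), and the extracellular matrix 7 higher and 0 lower (11 and 1, 0.61, 0.000121). All 43 oxidative phosphorylation genes had a higher effect in lambs, 0 past the threshold alone (median 0.54, camera adjusted p = 1.59e-07). Ribosomal proteins had 1 lower, RPS16 (0 higher and 15 lower adjusted over the list alone, median −0.57, camera adjusted p = 6.87e-09, and 0.183 with the ID prefix block). The hypoxia response had 5 lower (0 higher and 13 lower adjusted over the list alone, −1.06, 3.9e-06): CA9, NDRG1, ADM, MXI1 and, named after its values were seen, EGLN3. CA9 was near 0 in lambs (mean FPKM 0.011 in controls and 0 in IUGR), so an effect there could hardly show. The tricarboxylic acid cycle had 2 higher, CS and OGDH (5 and 0 adjusted over the list alone, 0.46, 0.000185). Fibroblast genes (0.52, 0.0113), with PI16 higher, atrophy genes (−0.60, 0.0113), with FBXO31 lower, myogenic regulators (0.24, 0.0347) and glucocorticoid response genes (−0.97, 0.0355) passed by camera too. Leaving out a library moved the cell cycle count from 13 to 5 without control fetus 1 and 6 without control fetus 3 or IUGR fetus 1, and the matrix count from 7 to 4 without control fetus 3 or IUGR fetus 1. The hypoxia count of 5 became 1 or 2 without control fetus 1, 2 or 3, IUGR fetus 1, control lamb 2 or 5 or IUGR lamb 0, 1 or 5, 8 without control fetus 0, 9 without IUGR lamb 4 and 12 without IUGR fetus 3. Ribosomal genes numbered 8 without control fetus 0, 11 without IUGR fetus 0 and 5 without IUGR lamb 4, and oxidative phosphorylation genes 3 without IUGR fetus 3 and 13 without IUGR lamb 4. Among genes, the calls of RPS16, CA9, NDRG1, ADM, EGLN3, CS, OGDH and FBXO31 each ended without 2 or more libraries. For all 8 control fetus 1 was among these (−0.74, −1.53, −0.90, −1.31, −2.17, 0.92, 0.98 and −0.72), and for all but CA9 also IUGR fetus 1 (−0.70, −0.87, −1.21, −1.69, 0.93, 0.92 and −0.53). The atrophy call ended without IUGR fetus 1 (−0.34), and with array weights the fibroblast (0.41), myogenic (0.33) and glucocorticoid (−0.84) calls ended. The myogenic call also ended with a pseudocount of 0.1 (0.30) or sex as a covariate (0.24), and the glucocorticoid call after quantile normalization (−0.98). Myogenic calls ended without control fetus 3 (0.37), IUGR fetus 0 (0.24) or 1 (0.32) or control lamb 1 (0.24), and glucocorticoid calls without control fetus 1 (−0.67) or 2 (−0.69), IUGR fetus 0 (−0.93) or 1 (−0.38), control lamb 0 (−0.89) or IUGR lamb 5 (−0.85). With the ID prefix block the matrix median was 0.30, that of oxidative phosphorylation 0.90, of the tricarboxylic acid cycle 0.92 and of myogenic regulators 0.39, each still past the threshold. So were the tricarboxylic acid cycle at 0.27 without IUGR fetus 0, myogenic regulators at 0.37 without IUGR fetus 3 and 0.45 without IUGR lamb 3, and cell cycle at 1.59 with a pseudocount of 0.1. Of the 614 genes, counts ran from 182 without IUGR fetus 1 to 1319 without IUGR lamb 4. The count was also under 400 without control fetus 1 (183), 2 (250) or 3 (244), control lamb 2 (343) or 5 (341), or IUGR lamb 0 (354), 1 (342) or 5 (323), 1204 without IUGR fetus 3, and 31 with the ID prefix block.

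**Figure D4:**
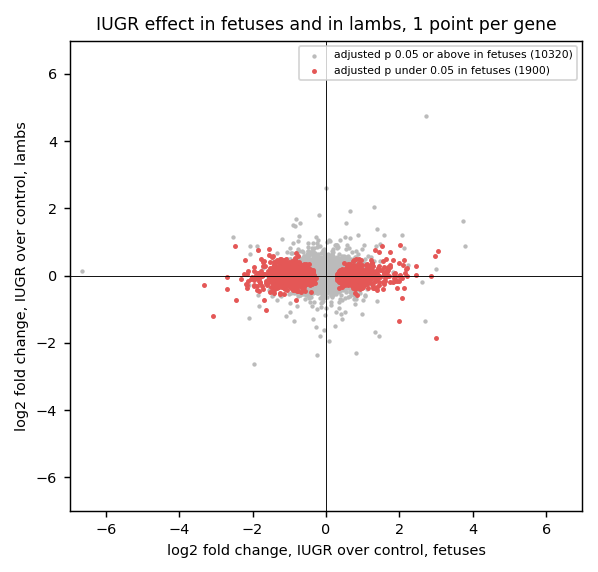
Log2 change with IUGR in lambs against that in fetuses, 1 point per gene, with the 1900 genes past the threshold in fetuses in red and the other 10320 in grey. Among genes with a symbol past the threshold in fetuses, changes there reach 3.04 for FKBP5 and −3.31 for PVALB, while 0 genes pass in lambs by limma, with 606 at an unadjusted p under 0.05.

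In control animals, the comparison of lambs with fetuses asked what changes in muscle between late gestation and the month after birth. Transcripts of fast fibres and of glycolysis and glycogen metabolism rose, and developmental sarcomere and imprinted transcripts fell. MB, myoglobin (chromosome 3, 178866679 to 178877963), rose 21.1-fold from a mean FPKM of 190 ± 54.1 (SD, n = 4) to 4199 ± 1617 (SD, n = 6; limma adjusted p = 4.67e-09). MYL4, the embryonic myosin light chain, fell by 7.46 on the log2 scale (SE 0.46, adjusted p = 2.64e-09), and PEG10, an imprinted gene, was at −3.55 (SE 0.22). In all, 4602 genes changed, 2586 higher and 2016 lower in lambs. After quantile normalization 2144 were higher and 2186 lower. UCP3 (3.79 ± 0.31 SE), BPGM (3.42 ± 0.19), SCN4B, ASB14, GPCPD1, ASS1 and PVALB also rose, and CASQ2 (−3.93 ± 0.37), HIF3A, ARHGAP36, LRRC38 and IGF2 (−2.74 ± 0.30) also fell. In all genes named so far, 6 of 6 lambs lay beyond all control fetuses. HBB fell by 2.66 (adjusted p = 0.0236, 4 of 6 lambs) and did not pass without control fetus 0 (−2.38), control fetus 3 (−2.44) or control lamb 5 (−2.23).

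Glycolysis and glycogen genes rose in control lambs in 20 of 26 and fell in 1, SLC2A1, with a median of 1.43 (camera adjusted p = 2.75e-11, adjusted p = 0.22 with an estimated correlation), among them PYGM (2.27 ± 0.15 SE) and PHKA1 (2.59 ± 0.15). Fast fibre genes rose in 12 of 13 (13 adjusted over the list alone, 1.27, 5.16e-07, adjusted p = 0.221 with an estimated correlation), including MYH1 (1.65 ± 0.19) and MYBPC2 (3.12 ± 0.25). All 9 developmental sarcomere genes fell (−1.15, 1.03e-06, adjusted p = 0.0816 with an estimated correlation), DLK1 by 2.42. Cell cycle genes fell in 19 of 24 and rose in 1, AURKA (−0.90, 1.03e-06, adjusted p = 0.374 with an estimated correlation), and ribosomal proteins fell in 19 of 26 (−0.50, 1.03e-06, adjusted p = 0.501 with an estimated correlation). Adipocyte genes rose in 9 of 13 (1.47, 0.000199, adjusted p = 0.374 with an estimated correlation), with ADIPOQ at 2.85 ± 0.51 SE and FABP4 at 2.56 ± 0.44. Imprinted genes fell in 8 of 13 and rose in 2, GRB10 and NNAT (−0.62, 0.000416, adjusted p = 0.221 with an estimated correlation). NNAT (0.83) no longer passed without control fetus 0 (0.64). Extracellular matrix genes fell in 10 of 29 (−0.53, 0.000241, adjusted p = 0.611 with an estimated correlation) and nerve and Schwann cell genes in 6 of 12 (−0.91, 0.000266, adjusted p = 0.308 with an estimated correlation), including PRX (adjusted p = 9.69e-07). Fatty acid oxidation (11 higher of 24, 1 lower, PPARGC1A), atrophy (10 higher of 24) and neuromuscular junction genes (7 lower of 13, 1 higher, SCN4A) passed too, with adjusted p = 0.374, 0.455 and 0.0816 with an estimated correlation. SLC2A1 (−1.06, adjusted p = 0.0357) no longer passed without control fetus 0 (−0.90), 2 (−1.12) or 3 (−1.05) or control lamb 0 (−1.04), 2 (−0.94), 4 (−1.07) or 5 (−1.06). PPARGC1A (−1.11) no longer passed without control fetus 3 (−0.49) or control lamb 2 (−1.01). Oxidative phosphorylation rose in 14 of 43 (0.43, 0.000416) and the tricarboxylic acid cycle in 11 of 18 (0.55, 0.00233), with adjusted p = 0.681 and 0.633 with an estimated correlation, and both lost the call after quantile normalization (0.12 and 0.26). Quantile normalization also moved fast fibre (0.82), fatty acid oxidation (0.33) and ribosomal medians (−0.81), and a pseudocount of 0.1 the cell cycle (−1.56) and imprinted medians (−1.01), all still past the threshold. Endothelium, at an adjusted p of 0.0503, passed as lower in 12 of the alternatives. Without control fetus 2 or 3 oxidative phosphorylation rose in 8, without control fetus 2 the tricarboxylic acid cycle rose in 7, and without control fetus 0 ribosomal proteins fell in 11. GRB10, NNAT, SLC2A1 and PPARGC1A were named after their values were seen.

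In IUGR animals, the same comparison of lambs with fetuses found 6034 genes changed, 3246 higher and 2788 lower. The balance turned to 2813 higher and 3146 lower after quantile normalization and to 3007 and 3013 after median-of-ratios scaling. Mitochondrial genes rose and ribosomal genes fell more widely than in controls, and the test of that difference is the one of the IUGR effects between ages given above (medians 0.54 and −0.57). That test lost both lists with an estimated correlation (adjusted p = 0.725) and by fry (adjusted p = 0.233 and 0.0825). PVALB rose 80.3-fold from a mean FPKM of 1.32 ± 0.941 (SD, n = 4) to 203 (n = 6; limma adjusted p = 1.23e-07) and MB 29.1-fold (adjusted p = 4.7e-10). ASS1 (4.67 ± 0.38 SE), IGFN1, CIB2, UCP3, GADL1 and, in 5 of 6 lambs beyond all IUGR fetuses, the serine synthesis enzyme PSAT1 (4.34, adjusted p = 0.00564) also rose. MYL4 (−4.77 ± 0.46), HIF3A, PEG10, PADI2, CCL1, ARHGAP36, AGT (−3.38 ± 0.40) and BCO1 (−3.19 ± 0.23) fell. Except for PSAT1, 6 of 6 lambs lay beyond all IUGR fetuses in each of these genes.

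Ribosomal proteins fell in 25 of 26 in IUGR lambs (median −1.11, camera adjusted p = 4.53e-13, adjusted p = 0.328 with an estimated correlation), RPS16 by 1.27 (SE 0.12). Oxidative phosphorylation rose in 40 of 43 (0.92, 1.92e-10, adjusted p = 0.56 with an estimated correlation), with NDUFS1 at 1.96 ± 0.25, and the tricarboxylic acid cycle in 17 of 18 (0.98, 1.02e-06, adjusted p = 0.506 with an estimated correlation), with CS at 1.57 ± 0.20 and a list median of 0.65 after quantile normalization. Fast fibre genes rose in 13 of 13 (1.31, 8.57e-08) and glycolysis in 19 of 26, with 2 lower, SLC2A1 and HK1 (1.56, 3.22e-08), each with adjusted p = 0.312 with an estimated correlation. HK1 (−0.60) no longer passed without IUGR fetus 1 (−0.27). Hypoxia response genes fell in 13 of 22 and rose in 1, LDHA (−0.95, 0.00295, adjusted p = 0.593 with an estimated correlation, −0.61 and still passing without IUGR fetus 1), and CA9 was listed at 0 in all 6 IUGR lambs. Developmental sarcomere genes fell in 7 of 9 (−1.42, 0.000625, adjusted p = 0.312 with an estimated correlation), imprinted genes in 9 of 13 with 2 higher, NNAT and GNAS (−0.88, 0.000746, adjusted p = 0.312 with an estimated correlation), and nerve genes fell in 8 of 12 with 1 higher, NGFR (−1.13, 0.00593, adjusted p = 0.503 with an estimated correlation). GNAS no longer passed after quantile normalization (0.41). Adipocyte genes rose in 8 of 13 and fell in 1, PNPLA2 (1.39, 0.0426, adjusted p = 0.773 with an estimated correlation), a list call that ended without IUGR fetus 0 (1.32), 1 (1.25) or 3 (1.41) or IUGR lamb 1 (1.13) or 5 (1.17), with array weights (1.35) or with sex as a covariate (1.29). PNPLA2 (−0.76) did not pass without IUGR fetus 1 (−0.44). In these lists NNAT, GNAS, SLC2A1, HK1, NGFR and PNPLA2 were named after their values were seen. Fetal and lamb animals share no ID prefix, so age and prefix cannot be told apart in either comparison of ages.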

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

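The tests of the ribosomal proteins and those of the fetal gene changes were chosen after the result was seen, while those of the lambs and the counts over other splits of the samples were set before.

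Ribosomal protein transcripts were higher in IUGR fetuses (median 0.58 over 26 genes), and 4 explanations were tested. Scaling between libraries alone is argued against, since after quantile normalization the median was still 0.398 (SE 0.047 over members, 26 of 26 positive). Each SE given here is over list members, which move together (estimated correlation 0.707), and does not measure the spread between animals. The library of IUGR fetus 1 alone is argued against as well, with a median of 0.497 (SE 0.035) without it, though 2 genes in place of 17 then passed. A larger share of fibroblasts is argued against, as their list was at −0.559 and its means in IUGR fetuses (−0.743 to −0.19) lay below the controls (−0.119 to 0.134). The macrophage list was at 0.27, but its means in IUGR fetuses (0.009 to 0.63) lay inside the control range (−0.522 to 0.766). Nerve and Schwann cell genes were at 0.35 and tendon genes at 0.27, and neither list passed by camera. A gain of a single cell type need not raise the markers of others, so a larger share of a cell type other than fibroblasts stays open. The animal ID prefix stays open: IUGR fetus 0, the IUGR fetus with the controls' prefix, had a list mean of 0.167, inside the control range of −0.25 to 0.358. IUGR fetuses 1, 2 and 3 were at 0.883, 0.444 and 0.881, so a difference tied to the prefix may underlie the rise, and growth restriction itself also stays open. IUGR fetus 0 is also the only female among the IUGR fetuses, so sex cannot be told apart from prefix among them.

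No gene passed in lambs (0 by limma, 606 at an unadjusted p under 0.05), against 1900 in fetuses. Of 441 genes changed 2-fold or more in fetuses, the lamb interval excluded a change of 50% of the fetal size or more in 329, 74.6% (median SE 0.288 in fetuses, 0.235 in lambs). The interval uses 1 spread per gene pooled over the 4 groups, so it cannot test a greater spread in lambs. The median SD between libraries was 0.216 in control lambs, 0.237 in IUGR lambs, 0.196 in control fetuses and 0.274 in IUGR fetuses. Both lamb medians lie between the fetal ones, which argues against a greater spread in lambs over all genes. Lower depth stays open, as relative depth was 0.61 to 1.2 in control and 0.62 to 0.93 in IUGR lambs, against 0.93 to 1.64 in control and 1.28 to 1.62 in IUGR fetuses. So does a greater spread in lambs in the 441 genes themselves. Persistence of the fetal change at a smaller size is argued against, since 885 of the 1900 genes, 46.6%, had the same sign in lambs, and 61 of 100 splits of the lambs gave a share as large (23.4% to 74.5%). Any split gives a count of at least 0, so that all 100 of 100 did (highest other 2) says nothing about chance. At an unadjusted p under 0.05, 25 of 100 splits gave as many genes as the 606 (highest other 1523). The age and recovery of the animals remain open and untested. So does the degree of restriction, as birthweight of the IUGR lambs was 62.3% of the control mean and weight of the IUGR fetuses 35.4%. The end of the heat also differed between the ages, and they share no ID prefix.

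The gene changes in fetuses were weighed for the ID prefix and for IUGR fetus 1. Low depth of IUGR fetus 1 is argued against by its relative depth of 1.62, above the fetal median of 1.475. The values speak against the prefix as the whole source but rest on 1 animal. In genes called from the other 3 IUGR fetuses, IUGR fetus 0 followed their change with a mean slope of 0.617 (0.49 to 0.727), 0.184 to 0.72 above that of a single control over the same genes, against an SD of 0.159 between the control slopes. As IUGR fetus 0 is the only IUGR fetus with the controls' prefix, how much of the larger change in the other 3 goes with prefix and how much with growth restriction cannot be told apart. IUGR fetus 0 is also the only female among the IUGR fetuses, so sex cannot be told apart from prefix among them. With sex as a covariate for all animals 1964 genes passed in fetuses, 1853 of them among the 1900. The weight of IUGR fetus 1 could not be settled either: without it 673 genes passed, 1.32 times the 511 of the highest other split of the 7 fetuses, and all 1900 genes kept their direction, 662 of them called (median size 0.714 before, 0.603 after).

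Chance as the source of the count is argued against in fetuses, where 1 of 35 splits, the real one with 1900 genes, gave as many and the highest other gave 153. A share of 1 of 35 is the smallest these splits allow, so chance is not excluded. That other split put control fetus 0 with IUGR fetuses 1, 2 and 3, and so parts the fetuses by prefix but for control fetus 0. Chance is also argued against, with 1 of 100 splits each, for age in controls (4602 genes, highest other 198), age in IUGR (6034, highest other 3758, from a split whose make-up was not examined) and the difference of IUGR effects (614, highest other 205).

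The IUGR effect differed between lambs and fetuses by limma's test of the difference itself. On the log2 scale, lambs minus fetuses, it was higher for CHRDL2 (3.36), PVALB (3.04), MYL4 (2.70), CCDC80 (2.67), SNAI3 (2.59), FAM78A (2.29), COL3A1 (2.25), COL1A2 (2.23), LRTM1 (2.22), TOP2A (2.11), PI16 (1.78), COL1A1 (1.74), CIB2 (1.67), CASQ1 (1.60), IGFBP7 (1.30), OGDH (1.06), GYG1 (1.03), CS (0.97), TPX2 (0.95) and COQ4 (0.73). It was lower for NDUFA4L2 (−2.48), BCO1 (−2.42), SNCG (−2.31), DLK2 (−2.21), GALNT15 (−2.16), EGLN3 (−2.15), AGT (−1.97), IGF1R (−1.92), CA9 (−1.68), MXI1 (−1.51), GRB10 (−1.42), ADM (−1.41), CYTIP (−1.36), EIF4EBP1 (−1.28), NDRG1 (−1.03), AURKA (−0.91), MAN2A2 (−0.79), RPS16 (−0.76), GCLM (−0.72) and FBXO31 (−0.67). BCO1, DLK2 and CA9 were near 0 in both lamb groups, so an effect in lambs could hardly show in them. By camera, list medians of the difference were 0.95 for cell cycle, 0.61 for extracellular matrix, 0.54 for oxidative phosphorylation, 0.52 for fibroblasts, 0.46 for the tricarboxylic acid cycle, 0.24 for myogenic regulators, −0.57 for ribosomal proteins, −0.60 for atrophy, −0.97 for glucocorticoid response and −1.06 for hypoxia response. With an estimated correlation none of the 10 passed (adjusted p = 0.725 each). The ribosomal call also ended with the ID prefix block, the fibroblast call with array weights and the atrophy call without IUGR fetus 1, and the myogenic and glucocorticoid calls ended under 7 and 8 alternatives.

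Single libraries stood apart from the rest of their group in 28 of 396 groups of values tested, where chance picks out 5%, about 1 in 20, or 19.8. The measure is the gap to the nearest other library over the whole range of the group. IUGR lamb 4 was apart most often, in 8: highest for HIF3A (0.782), GALNT15 (0.847), IGF1R (0.79), MXI1 (0.634) and NDRG1 (0.714), and lowest for CS (0.781), CCDC80 (0.672) and CASQ1 (0.653). No explanation of this was tested. IUGR lamb 3 was highest for PAX7 (0.834), PPARGC1A (0.6253) and SLC2A1 (0.646). Control fetus 0 was highest for GALNT15 (0.883), IL6R (0.856) and UGP2 (0.844) and lowest for IGFBP7 (0.899), and control fetus 3 highest for ADM (0.911) and DLL1 (0.88) and lowest for PYGM (0.833). IUGR fetus 1 was highest for IL6R (0.933) and EGLN3 (0.923) and IUGR fetus 3 for CS (0.849) and PHKG1 (0.87). Control lamb 0 was highest for PDK4 (0.788), control lamb 1 for BPGM (0.737) and DLK2 (1.0), control lamb 2 for PAX7 (0.759) and CA9 (1.0), and IUGR lamb 5 for DLK2 (1.0). In the DLK2 and CA9 groups at 1.0 the other lambs are all listed at 0.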

How the results depend on the processing

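Leaving out IUGR lambs 3 and 4 together, and the list counts without IUGR fetus 1, were chosen after seeing the data, and the other alternatives before. Of 8476 values of 407 named gene results under the alternatives, 7700 kept direction and side of the threshold, 746 lost the call (112 of them with the ID prefix block), 7 gained it and 23 reversed. Of 1200 values of lists that had passed, 1142 were kept, 57 lost the call and 1 reversed. Of 2298 values of lists that had not, 57 gained a call, in fetuses slow fibre, endothelium and inflammatory lists with the ID prefix block, smooth muscle without IUGR fetus 0, and glycolysis with array weights.

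The other gains were 13 in lambs, 20 for age in controls, 5 for age in IUGR and 14 for the difference. In lambs the matrix list passed as higher without control lamb 4, IUGR lamb 2 or IUGR lamb 4 and without IUGR lambs 3 and 4. Slow fibres passed as lower without control lamb 2 or IUGR lamb 0, adipocytes as lower without control lamb 0 or IUGR lamb 1, and macrophages as lower without IUGR lamb 4 and without IUGR lambs 3 and 4. Without IUGR lamb 2 fast fibres were lower and tendon genes higher, and without control lamb 1 amino acid stress genes were higher. For age in controls endothelium passed as lower in 12 settings and myogenic regulators in 4. Fibroblasts were lower after quantile normalization, amino acid stress genes higher with the replicate block, and glucocorticoid and clock genes higher without control fetus 3. For age in IUGR fatty acid oxidation passed as higher without a filter, and with array weights and without IUGR fetus 1 it was higher and endothelium lower. For the difference, fast fibres passed as higher in 6 settings and the clock as lower in 4. With the ID prefix block inflammatory and endothelium lists were lower, and so were macrophages without control fetus 0 and fatty acid oxidation without IUGR fetus 0. The cause of these gains was not tested.

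The count in fetuses was 614 with only the groups compared (6 residual degrees of freedom), 263 with the ID prefix block (IUGR fetus 0 alone against the controls, its spread taken from the other groups) and 997 with the replicate block, and from 673 without IUGR fetus 1 to 2474 without IUGR fetus 3. The difference of effects had 1380 genes with array weights, 31 with the ID prefix block and 12 with the replicate block, and from 182 without IUGR fetus 1 to 1319 without IUGR lamb 4. The lamb count was 0 in every setting run with limma, with 470 to 1081 genes at an unadjusted p under 0.05 when a library was left out. Age counts stayed within 1.5 times, though after quantile normalization the balance turned from more genes higher to more lower in both. With an estimated correlation 0 lists passed in fetuses, 0 in lambs, 0 for age in controls, 0 for age in IUGR and 0 for the difference, and by fry 6 in fetuses, 0 in lambs and 1 for the difference. The 6 were the ribosomal, hypoxia, cell cycle, myogenic, fibroblast and neuromuscular junction lists, the last of which camera had not called. Fry gave the matrix and fast fibre lists an adjusted p of 0.09 each, atrophy 0.106 and glucocorticoid response 0.144. The cause was not tested, except that the blocks and the smaller set of groups leave fewer degrees of freedom.

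Directions that reversed belonged, except HADHB and the heat shock list, to genes that had not passed. After quantile normalization in fetuses IGF2 was at −0.152, PAX7 at 0.055 and MYH1 at −0.033, and with array weights PAX7 was at 0.113. With the ID prefix block HADHB was at −0.005 and TNFRSF1A at 0.275 in fetuses and FBXO32 at 0.128 in lambs. Without IUGR lambs 3 and 4 PAX7 was at −0.088. With a library left out, PAX7 ran from −0.146 to 0.105 and PPARGC1A from −0.666 to 0.299 in fetuses. In lambs PAX7 ran from −0.086 to 0.328, ADRB2 from −0.29 to 0.069, SLC2A4 from −0.055 to 0.187, TNFRSF1A from −0.068 to 0.002, FBXO32 from −0.524 to 0.084, PPARGC1A from −0.246 to 0.044 and the heat shock list from −0.087 (without IUGR lamb 3) to 0.175. The cause was not tested. The fetal weight difference ran from −2.428 to −2.131 kg, with an exact permutation p of 0.0571 each, the smallest that 4 against 3 allows. Without counts, what depth limits could not be measured gene by gene.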

Other observations

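Vessel-wall, nerve, adipose and glycogen transcripts of IUGR fetuses fall outside the lists that passed, yet single genes in them moved. RGS5, a marker of pericytes, fell by 1.04 on the log2 scale (SE 0.21, limma adjusted p = 0.00388) and PRX, a gene of myelinating Schwann cells, rose by 0.94 (SE 0.23, 0.0113). The lipase gene PNPLA2 rose by 1.54 (SE 0.26, 0.00151) and the interleukin-6 receptor IL6R by 1.40 (SE 0.34, 0.0116). GYG1, the primer of glycogen synthesis, fell by 1.21 (adjusted p = 0.0027) and PHKG1, a subunit of phosphorylase kinase, by 0.84 (0.0044). All of these passed with each library left out in turn. With the ID prefix block, which rests on IUGR fetus 0, RGS5, PRX, PNPLA2, IL6R and GYG1 lost their call and PHKG1 kept it.

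The lists that hold them did not pass: smooth muscle and pericytes had 0 genes higher and 3 lower (median −0.30, camera adjusted p = 0.235), nerve and Schwann cells 1 and 1 (0.35, 0.235), adipocytes 1 and 0 (0.09, 0.431), inflammatory signalling 2 and 1 (0.10, 0.431) and glycolysis and glycogen 1 and 4 (−0.13, 0.335). Developmental sarcomere genes (1 and 3, −0.37, 0.252), slow fibre genes (0 and 1, −0.20, 0.427), adrenergic signalling (0 and 2, −0.14, 0.26), neuromuscular junction (0 and 2, −0.15, 0.335) and endothelium (1 and 1, 0.06, 0.928) did not pass by camera either. By fry the neuromuscular junction list passed as lower (adjusted p = 0.0372). With the ID prefix block, which rests on IUGR fetus 0, slow fibre genes passed as lower (−0.98, 0.0093) and endothelium (0.35, 0.00789) and inflammatory signalling (0.28, 0.027) as higher. The smooth muscle list passed without IUGR fetus 0 (0.0295) and the glycolysis list with array weights. Nor did amino acid stress (2 and 0, median 0.08 but mean −0.15, 0.726) or imprinted genes (1 and 1, 0.00, 0.962). Macrophage (0.27, 0.335), tendon (0.27, 0.435), erythroid (−0.27, 0.962), lymphocyte (−0.01, 0.969), clock (0.04, 0.7) and heat shock genes (−0.03, 0.928) had 0 genes past the threshold in fetuses by limma.

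A hypothesis was that the muscle of IUGR fetuses is delayed or advanced along the change from fetus to lamb, with its test set before the result was seen. Across 12220 genes, which are not independent replicates, the fetal IUGR change and the control change with age, taken from separate control fetuses, correlated at a mean of −0.024 over 6 assignments of the controls (−0.107 to 0.053). The sign changed between assignments, so neither a delay nor an advance of all genes together was found. Such a correlation cannot show lists that move in opposite senses. Ribosomal (median 0.58 with IUGR, −0.50 with age) and fast fibre genes (−0.41 and 1.27) went against the age change. Cell cycle (−0.84 and −0.90) and matrix genes (−0.49 and −0.53) went with it, in values whose shared controls favour the same direction. With all control fetuses in both comparisons the correlation was 0.067 and the covariance 0.0196, where simulated unchanged groups against shared controls gave 0.547 and 0.0351. The simulated correlation holds no effects and cannot be set against the observed one, while the covariance lay below what sharing alone adds. Genes called in both comparisons were lower in both in 307, where independence gives 176. They were higher in both in 172 (177), lower with IUGR and higher with age in 217 (225), and the reverse in 145 (138). Independence is not the value without a common change here, because shared controls favour the same direction, so the excess cannot by itself be read as a common change. Sharing would raise both same-direction classes, yet only the lower one stood above independence, and the source of this was not tested.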
